A study of Mus musculus with 15 samples.

How the data were processed

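RNA from large sensory neurons of mouse lumbar dorsal root ganglia was measured on Affymetrix whole-transcript arrays, in 15 samples of 5 groups with 3 biological replicates each. Per the labels, neurons over 26.9 µm were sorted by a fluorescent tracer given 5 days before the mice were killed and by green fluorescent protein under the CGRP promoter, and 50 ng of RNA per sample was amplified and labelled with biotin. The deposited values are log2 expression per probe set, normalized over the arrays by the authors. The submitters' processing notes name RMA and Partek, with no version, and do not state the log base, which was taken as log2 from the range of the values. The values were used as deposited. All 15 value columns were matched to a sample, and groups were taken from the sample titles.

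Of 35556 probe sets, 23410 were named in the probe table, 21789 with 1 gene symbol and 1621 with several, and the remaining 12146 were not analysed here. The gene identifier of 21698 probe sets matched the reference gene table, and 0 symbols were updated. For the 999 genes with more than 1 probe set the probe set with the highest mean over all arrays was used, which left 19938 genes tested. No dim gene was removed. The gene behind the fluorescent reporter is not among the genes tested, so the sort could not be checked on it and it was not analysed here.

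Differences between groups were tested in R 4.3.3 with limma 3.58.1. A linear model with 5 group means was fitted to all 15 arrays (10 residual degrees of freedom) with empirical Bayes moderation (prior degrees of freedom 4.325), and p was adjusted over all genes tested by Benjamini-Hochberg, with a threshold of 0.05. The comparisons were CFA paw with saline paw, CFA muscle and acid muscle each with saline muscle, CFA muscle with acid muscle, saline paw with saline muscle, and the difference of the CFA effects in muscle and paw. These comparisons, their tests, the gene lists, the rule for named genes and most of the alternatives below were chosen before the data were examined. A comparison of CFA paw with CFA muscle was added after seeing the data. All tests were two-sided. The replicate numbers were not used as a block in the tests reported, since the labels do not say that they mark a shared day or animal.

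The named genes of a comparison are the 12 largest rises and the 12 largest falls past the threshold or, where fewer than 20 genes pass, the 20 genes with the smallest p, given as values. Predicted, unnamed and receptor cluster loci are left out of these. List members past the threshold adjusted over the list alone, up to 4 members with the smallest p of each list that passes, and a fixed set of mechanosensitive and marker genes are named as well. A member of a list outside this rule that the text names was chosen after its values were seen. These are Sprr1a and Gal for CFA paw against saline paw and Apoe and Fabp7 for saline paw against saline muscle.

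Gene lists were tested with camera from limma, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 30 lists of a comparison. The lists cover sensory and voltage-gated channels, receptors, peptides, neuron subtypes, responses to injury, stress and inflammation, markers of other cell types that a sort could hold, and housekeeping machinery. They name 848 genes, of which 743 were measured, with 7 to 68 measured members per list. Beside camera, the correlation was estimated from the residuals, and fry, which tests whether the genes of a list move on balance one way, was run. The median and mean of a list are over its measured members.

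Each test was tested on simulated data with the spread of the 19938 genes. The noise was drawn independently for each gene, with the same spread on all arrays. The weights of the real arrays ran from 0.148 (saline paw replicate 1) to 7.18 (saline paw replicate 3). The shares below hold for the simulated setting and may not hold for the real arrays. For CFA paw against saline paw, 76% of genes changed by 1 on the log2 scale and 96% of those changed by 2 were recovered. The shares were 76% and 100% for CFA muscle and for acid muscle against saline muscle, 77% and 99% for CFA muscle against acid muscle, and 73% and 97% for saline paw against saline muscle. They were 33% and 91% for the difference of the CFA effects, whose median SE was 0.263 against 0.186 for the other comparisons. The number of arrays limits the precision. Correlations of effects across genes were set beside 100 simulated groupings of unchanged groups.

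The alternatives were centring of the arrays on their medians, cyclic loess between arrays, a filter on dim genes, a fit of only the arrays compared, array weights, an intensity trend with a robust prior, the mean of all probe sets of a gene, other thresholds, the replicate block, and leaving out each array in turn. The dim limit was 2.44, the 95th percentile of the mean levels of 1194 olfactory and vomeronasal receptor genes, and 13419 genes lay above it. Quantile normalization between arrays, leaving out the 3 arrays of lowest weight, the SD of each array as a covariate, and leave-one-out for the gene lists were added after seeing the data. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.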

Results

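Large sensory neurons from mouse dorsal root ganglia were profiled on 15 microarrays, in 5 groups of 3 biological replicates. The neurons came from lumbar levels 2 to 5, measured over 26.9 µm and were sorted by a retrograde tracer and by green fluorescent protein under the promoter of calcitonin gene-related peptide (CGRP), a peptide of many pain-sensing neurons. The skin groups held CGRP-positive neurons from mice that received saline (saline paw) or complete Freund's adjuvant (CFA paw), an emulsion with killed mycobacteria that causes inflammation. The muscle groups held CGRP-negative neurons from mice that received saline (saline muscle), CFA (CFA muscle) or acid (acid muscle). The saline groups are the study's controls, and its stated interest is in mechanosensitive molecules of myelinated afferents after inflammation.

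The median log2 expression of an array over 35556 probe sets ran from 2.65 to 2.92. The SD over 19938 genes ran from 1.66 to 1.80 on 5 of the 6 paw arrays and from 1.28 to 1.55 on the 9 muscle arrays. Saline paw replicate 1 had an SD of 1.42 and lay among the muscle arrays on the leading principal component, at −22.3, where the other paw arrays lay from 32.5 to 58.1 and the muscle arrays from −50.5 to −5.67. Correlations between arrays across genes ran from 0.939 to 0.991 within saline paw, with the lowest for replicates 1 and 2, and from 0.987 to 0.991 within CFA paw. With 3 arrays per group, the median standard error (SE) of a log2 difference was 0.186.

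**Figure D1:**
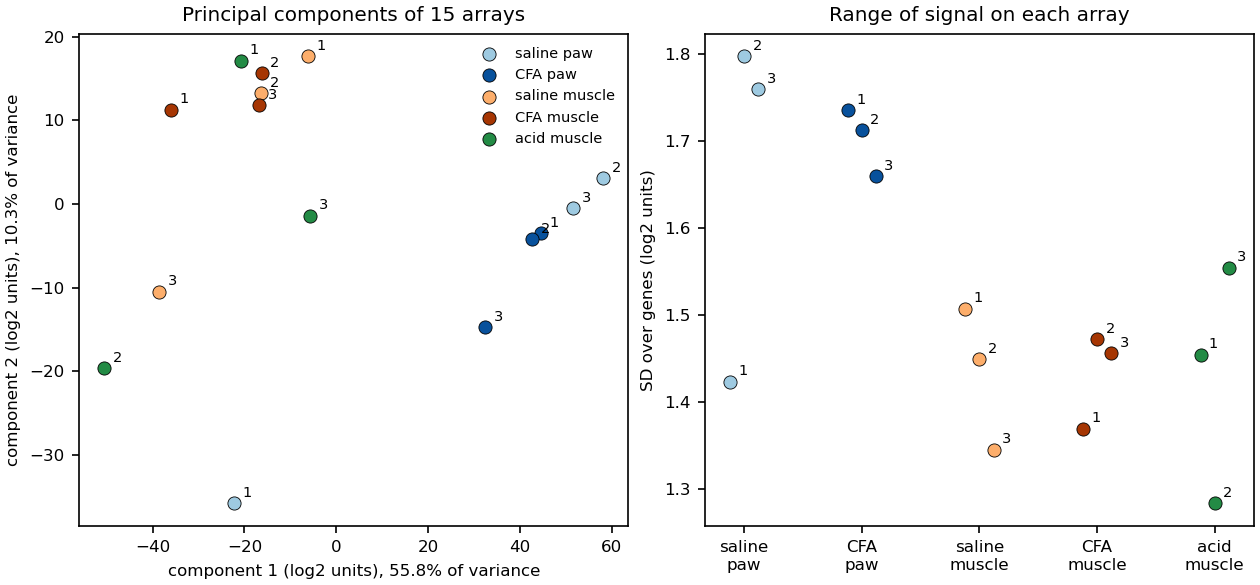
Principal components of the 15 arrays (left, log2 units) and the SD over genes of each array (right, log2 units), by group, with the replicate number at each point. Saline paw replicate 1, with an SD of 1.42, lies apart from the other 5 paw arrays, whose SD runs from 1.66 to 1.80.

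After saline, the CGRP-positive skin neurons expressed more of several receptors and peptides of pain-sensing neurons than the CGRP-negative muscle neurons. Htr3a, a subunit of the ionotropic serotonin receptor, was 9.52-fold higher in skin neurons (log2 expression 7.44 ± 0.86 against 4.19 ± 0.15, SD, n = 3 each). Ngfr, the low-affinity neurotrophin receptor, was 7.09-fold higher, and Asic3, an acid-sensing ion channel, was 5.49-fold higher (7.53 ± 0.87 against 5.08 ± 0.35, SD, n = 3 each). The muscle samples had more Grik1, a kainate receptor subunit (log2 difference −2.10, SE 0.321). They also had more Mrgprd, a receptor typical of non-peptidergic skin nociceptors (−1.90, SE 0.232), at 7.22 ± 0.40 in saline muscle (SD, n = 3). Whether the muscle sorts held only large muscle neurons was not tested, so it is open which neurons gave this signal. With limma, 373 genes were higher and 34 lower in saline paw than in saline muscle at a Benjamini-Hochberg adjusted p under 0.05, and 3361 genes had an unadjusted p under 0.05. The excess of higher genes depended on the scaling. After quantile normalization 213 were higher and 132 lower, and with the SD of each array as a covariate 164 were higher and 206 lower. In the deposited values, adjusted p was 0.000941 for Htr3a, 0.00108 for Ngfr, 0.0042 for Asic3, 0.00556 for Grik1 and 0.00143 for Mrgprd. These values rest on a spread pooled over all groups. Saline paw varied more than saline muscle for Htr3a, Ngfr (SD 0.81 against 0.17) and Asic3, though not for Mrgprd (0.29 against 0.40). The p-values of the former may thus be too small, and no gene passed in a fit of only the arrays compared. The other genes among the 12 largest rises were Smr2, S100a11, Tmem100, Gpx3, Thy1, Kcnv1, Tmem176b, Pcp4l1 and Htr1b, with log2 differences from 2.48 (Htr1b) to 3.46 (Smr2). The other genes among the 12 largest falls were Serping1, Il31ra, Cdh1, Ccdc68, Tceal9, Uaca, Nppb, Dpy19l2, Ceacam10 and Tdgf1, with log2 differences down from −1.54 (Serping1). In saline paw the means of Dpy19l2 and Tdgf1 lay under the dim limit of 2.44, the level that 95% of olfactory and vomeronasal receptor genes do not exceed. The size of their difference is thus uncertain.

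**Figure D2:**
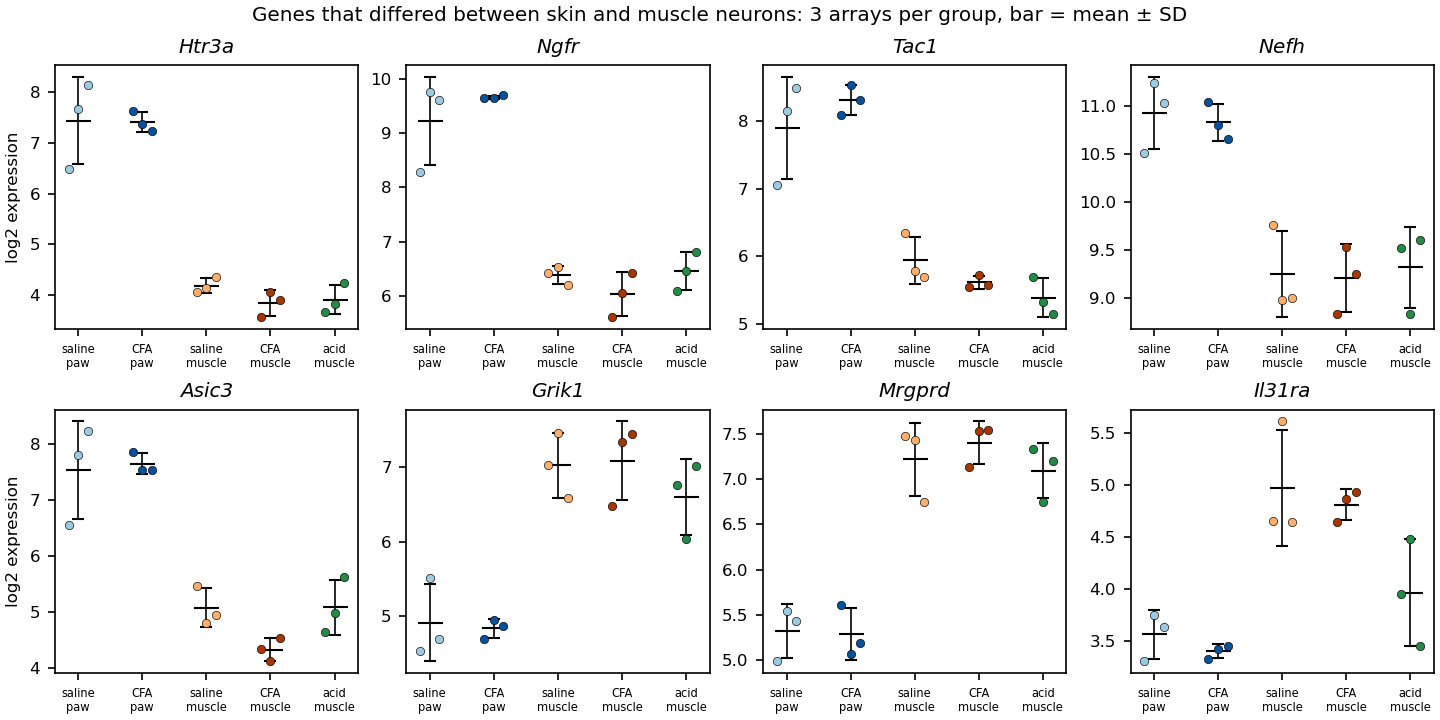
Log2 expression of 8 genes past the threshold between saline paw and saline muscle, for 3 arrays in each of the 5 groups, with the mean and SD as bars. Htr3a, Ngfr, Tac1, Nefh and Asic3 have higher means in both paw groups than in the 3 muscle groups, and Grik1, Mrgprd and Il31ra lower means.

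Markers of peptidergic nociceptors, the neurons that release CGRP and substance P, were higher in skin neurons as a group (median log2 difference 0.86 over 18 measured genes, camera adjusted p = 3.13e-07). The adjusted p = 0.356 with an estimated correlation. Of these genes 8 were higher and 0 lower over all genes tested, and 12 were higher and 1 lower adjusted over the list alone. They included Tac1, which encodes substance P (1.96, SE 0.294, adjusted p 0.00505), the stem cell factor receptor Kit (2.40, SE 0.329), the artemin receptor Gfra3 (2.07, SE 0.335) and the heat and capsaicin receptor Trpv1 (1.42, SE 0.343, adjusted p 0.0479). Markers of non-peptidergic and itch neurons were lower as a group (median −0.65 over 23 genes, camera adjusted p = 2.82e-07; adjusted p = 0.356 with an estimated correlation). Over all genes 3 of them were lower, namely Mrgprd, Il31ra (−1.41, SE 0.266) and Nppb (−1.02, SE 0.143), and 14 were lower adjusted over the list alone. The itch receptors Mrgpra3 (1.62, SE 0.338) and Mrgprx1 (1.48, SE 0.348) went the other way and were higher in skin neurons.

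Markers of large myelinated neurons were higher in skin neurons, with 3 of 26 genes past the threshold over all genes and 8 adjusted over the list alone (median 0.56, camera adjusted p = 1.52e-06; adjusted p = 0.356 with an estimated correlation). The 3 were the neurofilament genes Nefh (1.69, SE 0.27) and Nefl (1.64, SE 0.349) and the secreted protein gene Tafa1 (1.95, SE 0.332). Genes of the cytoskeleton and axonal transport were also higher (median 0.80, camera adjusted p = 6.76e-11; adjusted p = 0.408 with an estimated correlation), with 5 of 31 past the threshold over all genes and 13 adjusted over the list alone. They included Map1b (1.59, SE 0.352) and Stmn2 (1.58, SE 0.339). With the SD of each array as a covariate the median of the myelinated list was 0.085 (adjusted p 0.634) and that of the cytoskeleton list 0.0090 (adjusted p 0.986). Under cyclic loess between arrays the cytoskeleton median was 0.15 (adjusted p 0.0907).

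Among ion channels, calcium and HCN channels were higher in skin neurons (median 0.41, camera adjusted p = 0.000365; adjusted p = 0.271 with an estimated correlation), with Cacna2d2 (1.55, SE 0.247) and Cacna1e (1.11, SE 0.181) past the threshold over all genes and 3 of 19 adjusted over the list alone. The list's median fell to 0.17 (adjusted p 0.13) with the array SD as a covariate. Potassium channels were higher (median 0.17, camera adjusted p = 0.0174; adjusted p = 0.408 with an estimated correlation), with 6 of 46 genes past the threshold over all genes, among them Kcnq5 (1.99, SE 0.325), Kcnip3 (1.68, SE 0.334) and Kcnd1 (1.53, SE 0.27), and 9 higher and 1 lower adjusted over the list alone. Voltage-gated sodium channels had a median of 0.45 (camera adjusted p = 0.01; adjusted p = 0.452 with an estimated correlation), with 0 of 15 past the threshold over all genes in limma and 3 adjusted over the list alone. Under cyclic loess the sodium channel call was lost (median 0.10, adjusted p 0.486), as was the potassium channel call (median 0.047, adjusted p 0.691), and with the array SD as a covariate the sodium channel median was −0.069.

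Of 34 measured mechanically gated or mechanosensitive channels and partners, 3 were higher in skin neurons over all genes: Asic3, and the potassium channels Kcnk4 (1.41, SE 0.242, adjusted p 0.00942) and Kcnk10 (1.00, SE 0.232, adjusted p 0.0434), which respond to membrane stretch. Adjusted over the list alone, 7 were higher and 1 lower. The list as a group did not pass (median 0.043, camera adjusted p = 0.262). Piezo2, the main touch channel of these neurons, differed by 0.045 (SE 0.297; 0.30 without saline paw replicate 1 and −0.24 without saline muscle replicate 3) and Piezo1 by −0.57 (SE 0.247, adjusted p 0.259), and for both genes other probe sets gave the opposite direction. Trpa1 differed by −0.15 (SE 0.316; 0.11 without saline paw replicate 1), Stoml3, under the dim limit in saline paw, by −0.38 (SE 0.177) and Trpc6 by −1.28 (SE 0.335, adjusted p 0.0649).

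**Figure D3:**
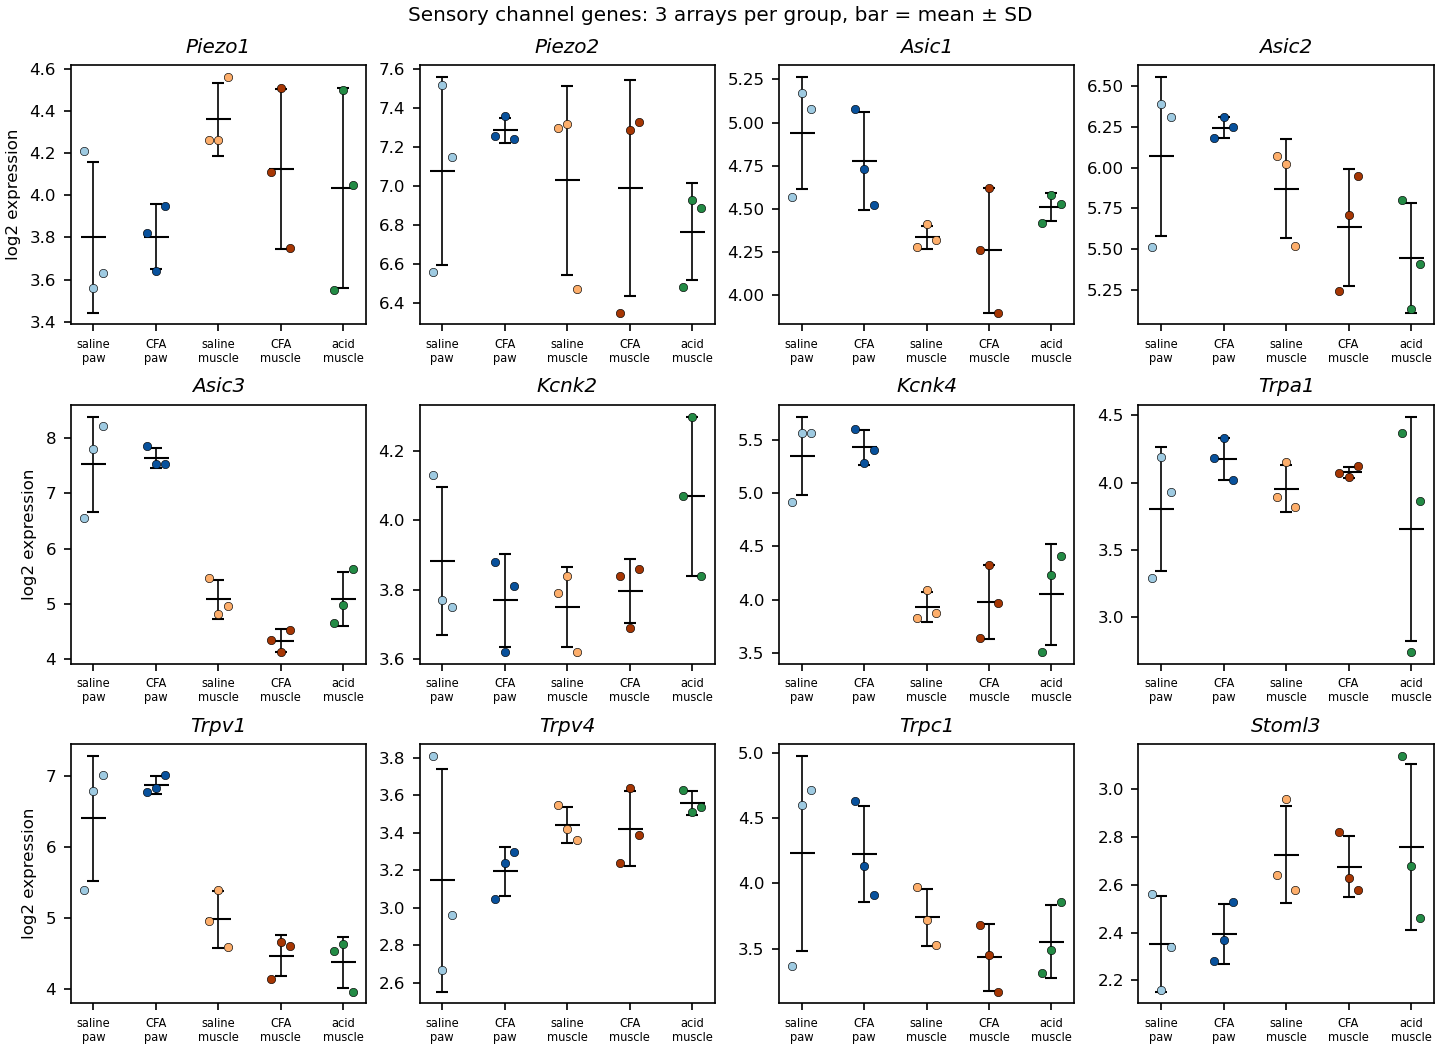
Log2 expression of 12 mechanosensitive or sensory channel genes on 3 arrays in each of the 5 groups, with the mean and SD as bars. Asic3, Kcnk4 and Trpv1 passed the threshold between saline paw and saline muscle, and Piezo2 did not.

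Receptors for opioids, neuropeptide Y, acetylcholine and related transmitters were higher in skin neurons (median 0.24 over 20 genes, camera adjusted p = 0.006; adjusted p = 0.271 with an estimated correlation), with Chrna3 (1.76, SE 0.362), Npy1r (1.48, SE 0.263, under the dim limit in saline muscle) and the delta opioid receptor Oprd1 (0.75, SE 0.176) past the threshold over all genes and 7 adjusted over the list alone. Neuropeptides did not pass as a group (camera adjusted p = 0.768). Their median was −0.074 and their mean 0.27, since Scg2 (2.09), Tac1, Adcyap1 (1.64), Calcb (1.19) and Vgf (0.85) were higher and Nppb lower over all genes, and 8 were higher and 3 lower adjusted over the list alone. Mitochondrial respiratory chain genes (median 0.25, camera adjusted p = 0.00143; adjusted p = 0.701 with an estimated correlation) and ribosomal protein genes (median 0.17, camera adjusted p = 0.0373; adjusted p = 0.731 with an estimated correlation) were higher in the deposited values, but turned to −0.20 (adjusted p 0.004) and −0.23 (adjusted p 9.31e-06) under cyclic loess. Over all genes 1 of 68 respiratory chain genes and 0 of 52 ribosomal protein genes passed in limma, and 0 and 0 adjusted over the list alone.

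Markers of several other cell types were lower in skin than in muscle neurons: endothelial and mural cells (median −0.34, camera adjusted p = 0.000192), macrophages (−0.18, 0.00402), fibroblasts (−0.24, 0.00582), Schwann cells and myelin (−0.47, 0.00715), neutrophils (−0.19, 0.00762) and lymphocytes (−0.24, 0.0111). The smallest adjusted p = 0.356 with an estimated correlation for these 6 lists. Over all genes 0 of their members were lower in limma, and the Schwann cell list held 1 higher gene, Ngfr, which these neurons also express. Macrophage, neutrophil, lymphocyte and fibroblast medians turned positive with the array SD as a covariate (0.025, 0.038, 0.022 and 0.0073). Several immune markers were dim. The macrophage marker Csf1r had a mean level of 2.82 over all arrays. Mmp8, Chil3 and Cd3g lay under the dim limit in both groups, while S100a9, Cd247 and Cd8b1 lay above it. The array medians of olfactory receptor genes were 1.569, 1.678 and 1.756 in saline muscle and 1.615, 1.514 and 1.504 in saline paw. The size of the lower immune medians is thus uncertain. Satellite glia markers did not pass (median 0.13, camera adjusted p = 0.262), nor did the acid and heat sensing receptors (median 0.12, 0.148), neurotrophic factors (0.044, 0.112), glutamate and GABA receptors (0.14, 0.0922), nerve injury genes (0.10, 0.278), inflammatory mediator receptors (−0.023, 0.314), inflammatory cytokines (0.021, 0.77), purinergic receptors (−0.093, 0.824), immediate early genes (0.048, 0.772), heat shock genes (0.14, 0.316), interferon response genes (−0.052, 0.983) or erythroid markers (−0.11, 0.179). The camera direction was up for the mediator receptors (mean 0.26), against the sign of their median, and down for the cytokines (mean 0.016) and the interferon genes (mean 0.084), against the sign of the mean.

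**Figure D4:**
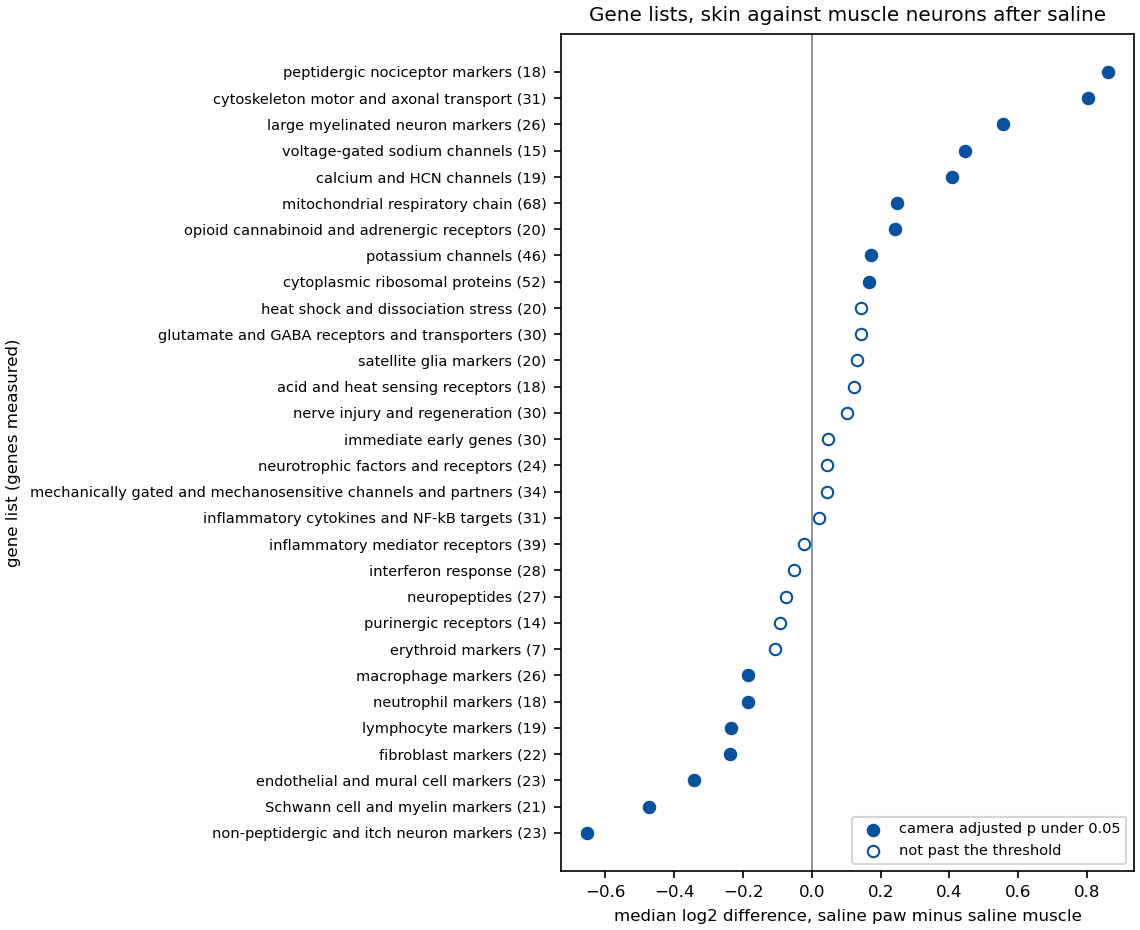
Median log2 difference between saline paw and saline muscle over the measured members of each of 30 gene lists, with the number of genes in parentheses. Filled points passed camera with the preset correlation at an adjusted p under 0.05, and 0 lists passed with an estimated correlation.

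The number of genes called between saline paw and saline muscle depended on single arrays: it was 3824 without saline paw replicate 1, 58 and 51 without saline paw replicates 2 and 3, and 217, 110 and 111 without saline muscle replicates 1, 2 and 3. A fit of only the 6 arrays compared called 0 genes, and target tissue, CGRP status, injection site and tracer site differ together between these groups.

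The comparison of CFA paw with saline paw asks how skin inflammation acts on large CGRP-positive skin neurons. Genes of nerve injury and regeneration were higher after CFA as a group, with positive differences in 26 of 30 genes (median log2 difference 0.37, camera adjusted p = 1.82e-14; adjusted p = 0.0363 with an estimated correlation). The members with the smallest p were Sema6a (0.72, SE 0.231), Flrt3 (0.57, SE 0.211) and Ecel1 (0.52, SE 0.205), and the growth cone gene Sprr1a differed by 1.67 (SE 0.847), galanin (Gal) by 0.90 (SE 0.524) and the injury transcription factor Atf3 by 0.39 (SE 0.389). Without saline paw replicate 1 these 3 differences were 0.91 for Sprr1a, 0.16 for Gal and 0.12 for Atf3. Neuropeptide genes were also higher as a group (median 0.082, mean 0.16, camera adjusted p = 0.00202; adjusted p = 0.0363 with an estimated correlation), with positive differences in 15 of 27 genes. Among them Adcyap1, which encodes the peptide PACAP, had a log2 expression of 7.15 ± 0.059 after CFA and 6.24 ± 0.60 after saline (SD, n = 3 each), and Vgf 6.05 ± 0.030 and 5.53 ± 0.094.

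No single gene passed in limma between CFA paw and saline paw, where 241 genes had an unadjusted p under 0.05 and about 997 would by chance. A count below chance, here and in the muscle comparisons, means that these p-values ran larger than chance alone gives. It is not evidence against an effect. No member of any list passed adjusted over the list alone. The genes with the smallest p included Sapcd1 (0.63), the ligand gene Alkal2 (0.77), Rem2 (−0.57), neuroglobin (Ngb, −0.66), Oprd1 (−0.62) and Prokr2 (0.80), all with an adjusted p of 1. Interferon response genes had a median of 0.13 (camera adjusted p = 0.0016; adjusted p = 0.298 with an estimated correlation), peptidergic nociceptor markers one of 0.29 (1.48e-05; adjusted p = 0.589 with an estimated correlation) and cytoskeleton genes one of 0.17 (0.00202; adjusted p = 0.921 with an estimated correlation). Of the mechanosensitive list 0 of 34 genes passed, over all genes or adjusted over the list alone, and the list's median was −0.0071 (camera adjusted p = 0.765). Piezo2 differed by 0.21 (SE 0.297), Asic3 by 0.12 (SE 0.347), Trpv1 by 0.47 (SE 0.343) and Piezo1 by 0.0064 (SE 0.247), whose other probe sets differed in direction. Without saline paw replicate 1 Piezo2 was at −0.043, Asic3 at −0.37, Trpv1 at −0.037, Piezo1 at 0.21 and Prokr2 at 0.49. Markers of macrophages (median −0.040, camera direction up, adjusted p = 0.936), neutrophils (0.027, 0.471) and satellite glia (0.093, 0.292) did not pass.

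Without saline paw replicate 1 the median of the injury list was 0.20 (camera adjusted p = 8.53e-06; adjusted p = 0.34 with an estimated correlation), that of the peptidergic markers −0.025 and that of the cytoskeleton genes −0.23 (adjusted p 0.00388). The neuropeptide call was lost without CFA paw replicate 1 (adjusted p 0.0702), without saline paw replicate 2 (0.0551) and, with an estimated correlation, without saline paw replicate 1 (0.214), and the interferon call without CFA paw replicate 1 (0.171).

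In the muscle neurons, the comparison of CFA muscle with saline muscle asks the same of muscle inflammation. Igfbp5, an insulin-like growth factor binding protein, had the smallest p, with a log2 expression of 5.30 ± 0.40 after CFA and 4.16 ± 0.45 after saline (SD, n = 3 each; difference 1.15, SE 0.23, limma adjusted p 1). Notch2 (0.59, SE 0.13), Jpt2 (0.80, SE 0.201), Ceacam10 (−0.76, SE 0.188) and Lhfpl5 (−0.54, SE 0.147), a partner of hair cell mechanotransduction channels, followed. Asic3 differed by −0.74 (SE 0.347), with no overlap between the 3 CFA and the 3 saline arrays, which chance gives, in either direction, for 10% of genes. Ribosomal protein genes were higher as a group, with positive differences in 43 of 52 genes (median 0.17, camera adjusted p = 0.000393; adjusted p = 0.992 with an estimated correlation), and Rps2 (0.48, SE 0.225) and Rps18 (0.58, SE 0.272) had the smallest p among them.

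Between CFA muscle and saline muscle 0 genes passed in limma, 518 had an unadjusted p under 0.05 and about 997 would by chance. The other 29 lists did not pass. The mechanosensitive list had a median of −0.031 (camera adjusted p = 0.903) and 0 of 34 genes past the threshold over all genes or adjusted over the list alone, with Piezo2 at −0.038 (SE 0.297; 0.28 without CFA muscle replicate 1 and −0.32 without saline muscle replicate 3) and Trpv1 at −0.51 (SE 0.343; −0.30 without saline muscle replicate 2). The ribosomal call was lost without saline muscle replicate 3 (median 0.084, adjusted p 0.077), and without CFA muscle replicate 1 the number of genes past the threshold was 8.

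Acid in the muscle is a model of muscle pain, and its comparison with saline muscle asks which genes of the muscle neurons it moves. Markers of peptidergic nociceptors were lower after acid as a group (median −0.32, camera adjusted p = 5.02e-05; adjusted p = 0.873 with an estimated correlation), with differences of −0.76 (SE 0.268) for Adcyap1 and −0.56 (SE 0.294; −0.36 without saline muscle replicate 1) for Tac1. Tyrosine hydroxylase (Th), also on that list, differed by −0.88 (SE 0.309). Unlike Tac1, Th was not higher in saline paw (5.01, 6.19 and 5.66) than in saline muscle (5.82, 6.79 and 6.05), so it is doubtful as a peptidergic marker here. Markers of non-peptidergic and itch neurons were lower as well (median −0.30, camera adjusted p = 7.7e-05; adjusted p = 0.873 with an estimated correlation). Of these Il31ra, the interleukin-31 receptor, was lower adjusted over the list alone (3.96 ± 0.52 after acid, 4.97 ± 0.56 after saline, SD, n = 3 each), and its partner Osmr differed by −0.67 (SE 0.215). Voltage-gated sodium channels had a median of −0.22 (camera adjusted p = 0.014; adjusted p = 0.873 with an estimated correlation), with Scn9a at −0.58 (SE 0.339; −0.38 without acid muscle replicate 2 and −0.88 without saline muscle replicate 3).

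Over all genes, 0 passed in limma between acid muscle and saline muscle, 568 had an unadjusted p under 0.05 and about 997 would by chance. Those with the smallest p included Rabggtb (−0.59), Lhfpl5 (−0.60), Necab2 (0.49) and Lgi4 (0.57), all with an adjusted p of 1. Necab2 was higher adjusted over the list of large myelinated neuron markers alone. Of the mechanosensitive list 0 of 34 genes passed, over all genes or adjusted over the list alone (median 0.0053, mean −0.062, camera adjusted p = 0.52), with Kcnk2 at 0.32 (SE 0.149; 0.21 without acid muscle replicate 2), Piezo2 at −0.26 (SE 0.297; −0.11 without saline muscle replicate 2 and −0.54 without replicate 3) and Asic3 at 0.0071 (SE 0.347; 0.22 without acid muscle replicate 1 and −0.26 without replicate 3). The acid and heat sensing receptors had a median of 0.00079 and a mean of −0.049 (camera adjusted p = 0.662). The sodium channel call was lost without acid muscle replicate 2 (median −0.091, adjusted p 0.235), saline muscle replicate 1 (−0.21, 0.0657) or saline muscle replicate 2 (−0.10, 0.58), and the call of non-peptidergic and itch markers without saline muscle replicate 2 (−0.069, 0.354).

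CFA muscle and acid muscle share no array in their direct comparison, which asks whether the treatments of the muscle differ. Markers of non-peptidergic and itch neurons (median 0.31, camera adjusted p = 0.00412) and of peptidergic nociceptors (0.19, 0.00423) were higher after CFA than after acid, with Il31ra at 0.85 (SE 0.266) and Nppb at 0.46 (SE 0.143) on the first list. Th, on the peptidergic list but doubtful as such a marker here, differed by 0.82 (SE 0.309). Tafa4, on the same list, differed by 0.62 (SE 0.261) but was lower in saline paw than in saline muscle (−0.62, SE 0.261). It is thus doubtful as a peptidergic marker here too. Isl2, which was higher in saline paw (0.56, SE 0.224), differed by 0.47 (SE 0.224), and Trpv1 by 0.096 (SE 0.343). Markers of large myelinated neurons (−0.22, 0.0103), respiratory chain genes (−0.21, 0.0103) and immediate early genes (−0.20, 0.0462) were lower after CFA, with Kcna1 at −0.47 (SE 0.298) and Ndufa11 at −0.97 (SE 0.404). Of the immediate early genes Nr4a3 had the smallest p, at a mean level under the dim limit after CFA. For each of these 5 lists the adjusted p = 0.96 with an estimated correlation. In limma 0 genes passed, over all genes or adjusted over a list alone, and 626 had an unadjusted p under 0.05, where about 997 would by chance. The genes with the smallest p included Hebp2 (−0.51), Eid2 (−0.72), Furin (−0.60) and Gbp7 (0.81). Abi3bp and Ptgs2 were among them too, but lay under the dim limit in 1 of the groups. Asic3 differed by −0.75 (SE 0.347). Without acid muscle replicate 3 Asic3 differed by −0.48, Kcna1 by −0.16 and Ndufa11 by −0.40.

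Every 1 of these 5 list calls was lost without some array. Without acid muscle replicate 3 the respiratory chain median turned to 0.068 (adjusted p 0.0456) and the myelinated median was −0.0025 (0.946). Without acid muscle replicate 2 the non-peptidergic median was 0.063 (0.165) and the peptidergic adjusted p 0.0716, and without acid muscle replicate 1 the immediate early median was −0.056 (0.965).

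The difference of the CFA effects, muscle minus paw, tests whether CFA acted differently on the sorted muscle and skin neurons. Nerve injury and regeneration genes had a more negative effect in muscle than in paw, with positive differences in only 4 of 30 genes (median −0.43, camera adjusted p = 6.49e-09; adjusted p = 0.106 with an estimated correlation), as did neuropeptide genes (−0.26, 0.00184; adjusted p = 0.055 with an estimated correlation). The CFA effect on Adcyap1 was lower by 1.60 (SE 0.38) in muscle than in paw, past the threshold adjusted over the list alone in the neuropeptide and peptidergic lists, with a limma adjusted p of 1 over all genes. Part of this was a higher mean after CFA in the paw (0.91, SE 0.268). There saline paw replicate 1 had the lowest saline value, 5.65 against 6.22 and 6.85. Peptidergic markers (−0.30, 0.00116; adjusted p = 0.869 with an estimated correlation) and cytoskeleton genes (−0.25, 0.0307; adjusted p = 0.929 with an estimated correlation) also passed. In limma 0 genes passed over all genes and 325 had an unadjusted p under 0.05, with Igfbp5 (1.39, SE 0.326) and Jpt2 (1.12, SE 0.285) among the smallest p. The mechanosensitive list did not pass (median −0.029, camera adjusted p = 0.84), and Asic3 had a difference of −0.86 (SE 0.491; −0.37 without saline paw replicate 1).

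**Figure D5:**
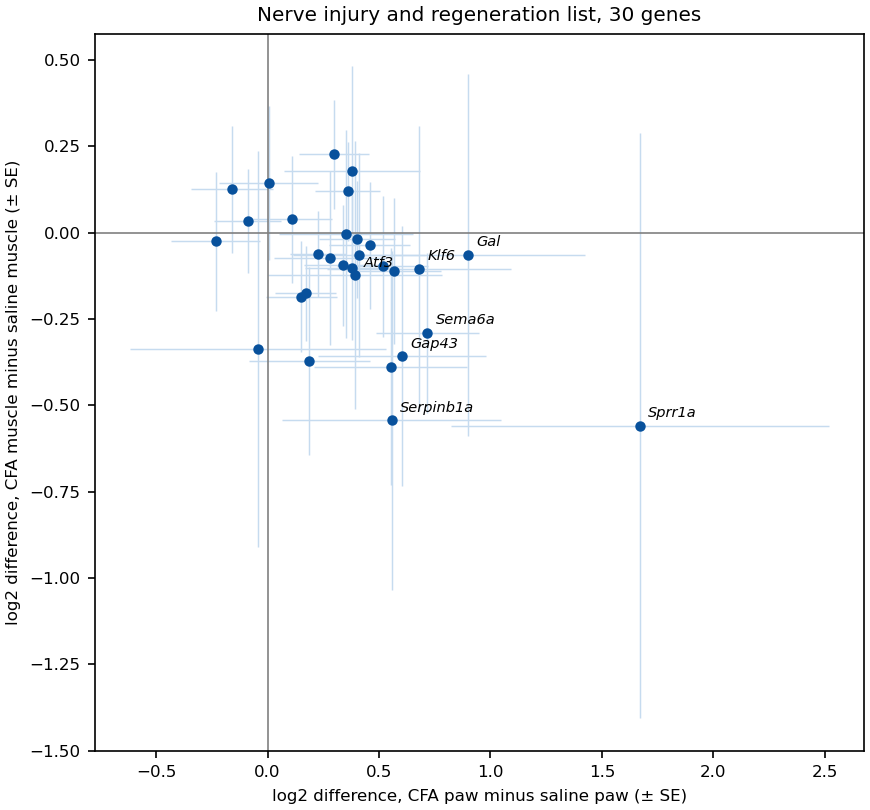
Log2 difference after CFA in the paw (horizontal axis) and in the muscle (vertical axis) for the 30 genes of the nerve injury and regeneration list, each with its SE. In the paw 26 of the 30 genes lie above 0, while 0 genes passed the threshold on their own in either tissue.

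Without saline paw replicate 1 the median difference of the CFA effects was 0.025 for peptidergic markers and 0.10 for cytoskeleton genes. For the injury list it was −0.30 (adjusted p = 0.64 with an estimated correlation).

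Across genes, the effects of acid and of CFA in the muscle had a Pearson correlation of 0.433. Both are measured against the same saline arrays, and unchanged groups simulated against shared controls gave a median of 0.49, with a 5th to 95th percentile range from −0.078 to 0.90. The CFA effects in paw and muscle, which share no arrays, had a correlation across genes of −0.033, against a simulated median of 0.019. Genes are not independent replicates, so no p was computed for these correlations.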

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

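The tests of a muscle sample under a paw label, of other cells in the muscle sorts, of the share of higher genes and the comparison of CFA paw with CFA muscle were chosen only after the result was seen.

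The CFA effects differed between muscle and paw in the test of the difference itself for 4 gene lists, and for 1 gene only when adjusted over a list alone. The median difference, muscle minus paw, was −0.428 for nerve injury and regeneration genes, −0.258 for neuropeptides, −0.298 for peptidergic nociceptor markers and −0.249 for cytoskeleton, motor and axonal transport genes. Adcyap1 differed by −1.60, with an adjusted p of 1 over all genes. With an estimated correlation 0 of these lists passed, and without saline paw replicate 1 the medians of the peptidergic and cytoskeleton lists turned to 0.0247 and 0.104. In limma 0 genes passed over all genes tested, so that 100 of 100 drawn splits of the 12 arrays gave as many genes by construction, with 2 as the highest of the other splits, and the splits decide nothing about chance here.

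Saline paw replicate 1 lay between the other paw arrays and the muscle arrays over genes that separate them. On the leading principal component it lay among the muscle arrays (−22.3, against −50.5 to −5.67). A narrower range of signal may account for its position: over 11190 genes at a like level in CFA paw and in the CFA and acid muscle groups, its slope on the other saline paw arrays was 0.843 (bootstrap SE over genes 0.004), below the 0.867 to 1.08 of the other 14 arrays, though close to acid muscle replicate 2 at 0.867. That SE does not measure the spread between arrays. RNA of muscle-type neurons is argued against, since 26 genes higher in muscle exceeded level-matched genes by 0.0555 on that array, within the −0.0292 to 0.111 of the 3 CFA paw arrays. Its position over 26 genes higher in muscle and 770 higher in paw was 0.646 on a line from the other paw arrays (0) to the muscle arrays (1), below all 9 muscle arrays (0.758 to 1.20). This argues only weakly against a muscle sample under a paw label. The gap is small beside the spread of the muscle arrays, and the CFA and acid muscle arrays also served to pick the genes. A biological difference between the replicate animals was not tested.

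Of the genes called between saline paw and saline muscle, 91.6% were higher in paw, and the paw arrays other than saline paw replicate 1 have a wider range of signal than the muscle arrays. As the whole cause of the calls a wider range is argued against, because 57.5% of the called genes were still called in the same direction after quantile normalization and 74.7% under cyclic loess, although with the array SD as a covariate, which goes with the groups, 34.2% were. A split of these saline arrays by range of signal called 2026 genes, against the real 407. That split still sets saline paw replicates 2 and 3 against saline muscle replicates 2 and 3, so it cannot tell range from tissue. Range may still account for part of the calls. For the share of higher genes it cannot be told apart from a true excess: the share was 61.7% after quantile normalization, 69.1% under cyclic loess and 44.3% with the array SD as a covariate. More cells other than neurons in the muscle sorts could also contribute and cannot be excluded. Satellite glia markers, however, had a median of 0.131, with Apoe at 0.77 (SE 0.35) and Fabp7 at 0.68 (SE 0.36), short of the threshold. Fabp7 was at 1.08 (adjusted p 0.0367) without saline paw replicate 1 and at 0.32 without replicate 2. Whether the sort by size and tracer removed such cells was not tested. Some of their markers were bright, with mean levels of 9.88 for Apoe, 9.41 for Fabp7 and 9.4 for the Schwann cell marker Pmp22. The macrophage marker Csf1r was dimmer, at 2.82. Target tissue and CGRP status stay open as biological explanations, since the design joins them.

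Nerve injury and regeneration genes were higher in CFA paw than in saline paw by a median of 0.368. Without saline paw replicate 1 the median was 0.196 and still passed camera with the preset correlation, which argues against that array as the whole cause, although the call with an estimated correlation was lost. Of the 10 splits of the 6 paw arrays, 2 gave an absolute median as large, with 0.398 for CFA paw replicates 1 and 2 with saline paw replicate 2, and 10 splits are too few for a share under 0.05. An effect of CFA on injury genes may therefore be considered a hypothesis, with its size near 0.196 without the array in doubt.

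The 10 splits of 6 arrays are also too few for a share under 0.05 in the gene counts. For CFA paw, CFA muscle and acid muscle against saline, and for CFA muscle against acid muscle, the real count was 0, the highest other count 0, and all 10 splits gave as many, which a real count of 0 fixes. For saline paw against saline muscle 2 of the 10 splits gave as many genes as the real 407. The other, saline muscle replicate 1 with saline paw replicates 2 and 3 against the rest, gave 2026, several times the real count. It sets the 3 arrays of widest range (SD over genes 1.507 to 1.797) against the 3 of narrowest (1.345 to 1.449). This split called more genes than the grouping by tissue, but it is not free of tissue. It still sets saline paw replicates 2 and 3 against saline muscle replicates 2 and 3, and puts saline paw replicate 1 with the latter. It thus cannot separate range of signal from tissue. The splits that put saline paw replicate 1 with saline muscle replicates 1 and 2, or 1 and 3, gave 0 and 2 genes. For CFA paw against CFA muscle 1 of the 10 splits, the real one, gave 1279 genes, and the highest other count was 0.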

How the results depend on the processing

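Alternatives chosen only after seeing the data were quantile normalization, leaving out the 3 arrays of lowest weight, the array SD as a covariate, leave-one-out and the estimated correlation without saline paw replicate 1 for gene lists, and all alternatives of CFA paw against CFA muscle. The cause of the changes was not tested, except that other thresholds and fewer arrays change the count by construction. Signal over background limits dim genes: 13419 of 19938 genes lie above the dim limit. The planned check of the reporter gene was not run, since no probe set names it. Scaling moved the median of all genes by at most 0.109, for CFA paw against CFA muscle with centred arrays.

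The count of genes past the threshold, 0 in the 4 treatment comparisons and in the difference of the CFA effects, stayed 0 under both planned scalings, the dim filter, the trend with a robust prior, the mean of probe sets, an adjusted p under 0.10, only the arrays compared, the replicate block, quantile normalization and the array SD as a covariate. Array weights gave 125 for CFA paw, an unadjusted p under 0.01 with a fold of at least 1.5 gave 13 for CFA paw, 33 for CFA muscle, 30 for acid muscle, 43 for CFA against acid muscle and 31 for the difference of the CFA effects, and without the 3 arrays of lowest weight acid muscle had 1. Leaving out each array gave 0 to 8 for CFA muscle, 0 to 6 for CFA against acid muscle and 0 to 1 for the difference of the CFA effects, each highest without CFA muscle replicate 1, and 0 throughout for CFA paw and acid muscle.

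For saline paw against saline muscle, 407 became 213 with centred arrays, 0 with only the arrays compared, 7379 with array weights, 896 at an adjusted p under 0.10, 1166 at the unadjusted threshold with a fold, 3378 without the 3 arrays of lowest weight, and 51 to 3824 leaving out each array. It was 459 under cyclic loess, 345 under quantile normalization, 370 with the array SD as a covariate and 316 with the replicate block. For CFA paw against CFA muscle, 1279 became 3209 with only the arrays compared, 4054 with array weights, 2067 at an adjusted p under 0.10, 695 under quantile normalization, 3703 without the 3 arrays of lowest weight, 444 with the array SD as a covariate, and 527 to 832 leaving out each array.

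For gene lists, an estimated correlation left 2 of 5 lists for CFA paw and 0 for each other comparison, fry passed 8 lists for saline paw against saline muscle, 4 of them among the 16 of camera in the same direction, and 0 for CFA paw, CFA muscle, acid muscle, CFA against acid muscle and the difference of the CFA effects, and an estimated correlation without saline paw replicate 1 left 0 for CFA paw, saline paw against saline muscle and the difference of the CFA effects. Without the 3 arrays of lowest weight 13 lists passed for CFA paw, 5 for CFA muscle (1 before) and 8 for acid muscle (3 before). Acid muscle had 6 under cyclic loess and 5 with the array SD as a covariate, and saline paw against saline muscle had 10 with the dim filter, 10 under cyclic loess and 8 with the array SD as a covariate. Leaving out each array gave 2 to 14 lists for CFA paw, 1 to 3 for CFA muscle, 1 to 9 for acid muscle, 3 to 7 for CFA against acid muscle and 3 to 8 for the difference of the CFA effects.

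The correlation of the acid and CFA effects in muscle ran from 0.307 to 0.615 leaving out each array, and that of the CFA effects in paw and muscle from −0.193 to 0.0783.

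Of the checks of named genes under these alternatives, 0 reversed a called gene. For saline paw against saline muscle the same result held in 787 of 1070 checks and a call was lost in 256. A gene not called counts as the same if it stays uncalled and its difference moves by less than its SD within groups, even where the sign turns. For CFA paw against saline paw no gene was called, so no call could be lost. There 286 of 306 checks counted as the same, 14 moved further and 6 gained a call.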

Other observations

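The comparison of CFA paw with CFA muscle was chosen only after the data were seen. Skin neurons after CFA expressed more Ngfr, the low-affinity neurotrophin receptor, than muscle neurons after CFA (log2 difference 3.63, SE 0.317), more Asic3 (3.32), Gap43 (3.27, SE 0.377) and Adcyap1 (3.24), and less Prkcq (−2.30), Grik1 (−2.24) and Mrgprd (−2.11). Sprr1a, a growth cone protein of regenerating neurons, was also higher (4.14, SE 0.847), but its call was lost without CFA muscle replicate 1 (3.32, adjusted p 0.0571), without CFA paw replicate 1 (3.69, adjusted p 0.0554) and with the array SD as a covariate (2.51, adjusted p 0.172). With limma 1146 genes were higher and 133 lower in CFA paw, and 4153 had an unadjusted p under 0.05. The total of 1279 became 695 under quantile normalization (477 higher, 218 lower) and 444 with the array SD as a covariate (232 higher, 212 lower), corrections that could also remove a true excess of higher genes. Leaving out 1 array gave from 527 genes (CFA muscle replicate 1) to 832 (CFA muscle replicate 3). Of the 373 genes higher in saline paw than in saline muscle 329 were also higher in CFA paw than in CFA muscle (21.4 expected if independent), and of the 34 lower genes 9 were also lower (0.227 expected). The differences had a correlation of 0.845 across genes, which are not independent replicates. Both comparisons come from 1 fit and share each gene's estimate of the spread. Most paw arrays also have a wider range of signal than the muscle arrays in both. The overlap and the correlation therefore cannot separate a repeated tissue difference from the shared range.

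In that comparison nerve injury and regeneration genes were higher in CFA paw as a group (median 0.51, camera adjusted p = 4.02e-06; adjusted p = 0.174 with an estimated correlation), with 7 of 30 higher over all genes, among them Gal (2.74, SE 0.524, under the dim limit in CFA muscle), Serpinb1a (2.85, SE 0.491) and Hspb1 (1.84, SE 0.271), and 11 higher and 1 lower adjusted over the list alone. With the array SD as a covariate the calls of Gal (1.68, adjusted p 0.122) and Serpinb1a (1.66, adjusted p 0.0555) were lost. Voltage-gated sodium channels were higher (median 0.80, camera adjusted p = 0.000151; adjusted p = 0.307 with an estimated correlation), with 5 of 15 past the threshold over all genes and 9 adjusted over the list alone, a call lost with the array SD as a covariate (median 0.15, adjusted p 0.724). Schwann cell and myelin markers were lower (median −0.88, camera adjusted p = 0.000836; adjusted p = 0.324 with an estimated correlation), with 1 of 21 genes higher and 3 lower over all genes, and 2 higher and 11 lower adjusted over the list alone. Tracer was placed in a nerve for skin neurons and in the muscle for muscle neurons, so tracer site differs with tissue here too.

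After saline, a few genes of stress and antiviral responses were higher in skin than in muscle neurons although their lists did not pass. They were the interferon-induced genes Oasl2 (log2 difference 1.19, SE 0.247), Ddx58 (1.06, SE 0.231) and Rtp4 (0.55, SE 0.134) and the chaperone genes Bag3 (1.46, SE 0.298) and Hspb1 (1.28, SE 0.271), with limma adjusted p from 0.0247 (Bag3) to 0.0488 (Rtp4). The prostaglandin receptors Ptger1 (1.69, SE 0.194) and Ptgir (1.41, SE 0.273) were also higher, among 4 of 39 inflammatory mediator receptors past the threshold over all genes.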
